A study of Mus musculus with 28 samples.

How the data were processed

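Liver RNA of 28 male C57BL/6 mice in 7 groups of 4 was measured by RNA sequencing. Total RNA was extracted with Trizol and stranded poly(A) libraries were made with the TruSeq Stranded mRNA kit, per the labels' protocols. The tools bcl2fastq, STAR 2.5.1b, Cuffnorm, Cufflinks 2.2.1 and Cuffdiff and the mouse build GRCm38 were used per the submitters' processing notes, which give no role or order of these tools. Whether counting used the strand is not given in the sources used here, so an antisense gene and its partner are treated as uncertain.

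The data used are 10 gene tables of pairwise group comparisons, each listing 47719 genes. The FPKM values (fragment counts scaled to transcript length and to library size) are the authors' deposited group values from Cuffdiff, per the file headers, with 1 value per group and none per animal. The log2 fold changes are the authors' deposited values, the second group over the first, per the file headers. The test statistic is a score that the authors deposited beside each fold change, and the p-value and the q-value (the p adjusted for the number of genes tested) are the authors' deposited Cuffdiff output. The smallest deposited p was 5e-05 in every table, and the smallest q lay between 0.000346 and 0.00268. A gene was called when its status was OK and its deposited q was under 0.05. This matched the authors' own significance flag in every table.

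Because the tables hold group values, the spread between animals enters only through the authors' test, and no library could be left out, compared with its replicates or inspected alone. The labels call the samples separate animals of a group. The depth of each sample is unknown: the low FPKM values were continuous, with no steps of a single read, as group values pool 4 libraries. The FPKM of a group summed to between 706031 and 915996 over all genes in a table. Between 15208 and 16144 genes were tested in a table. An FPKM is given with the table it comes from, since tables were scaled separately: the same group's values in different tables differed by up to 0.194 (log2) as a constant. Apart from that constant they deviated by a median of at most 0.000762 (log2) over 6356 genes, against at least 0.0740 between different groups, which settled which vehicle group each table used.

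Comparisons were the diet effect in each vehicle group against lean control, each drug group against its own vehicle group, and each drug group against lean control. The tropifexor doses of 0.1, 0.3 and 0.9 mg/kg were assigned to the groups named low, mid and high in rising order, because the labels do not pair them. The treatment field of the vehicle samples lists OCA or tropifexor, while their titles name vehicle; the titles and the names of the comparisons were followed, and every drug effect against vehicle rests on that reading. That the vehicle animals received the NASH diet was read from the series' design text and the names of the comparisons.

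Effects were compared by the difference of their log2 fold changes. Each fold change was given the standard error implied by its value and its test statistic, variances were added, and a normal p was adjusted by the Benjamini-Hochberg method over the genes with status OK in both tables; a difference was called at an adjusted p under 0.05. An exact test of groups of 4 needs values per animal, so no exact p could be had, and single genes are given with the difference, its normal 95% interval and the call. Genes with a fold change that was not finite, that differed from the ratio of the deposited FPKM by 0.01 or more (1 to 4 tested genes in a table), or with a statistic of 0 were left out. The normal z of the deposited p was 2.03 to 2.05 times the test statistic in the median gene of each table, taken over genes with p between 0.0002 and 0.9, so the implied standard error is about 2 times as wide as the deposited p assumes. A rescaled standard error, the implied one divided by that factor, was therefore added as an alternative chosen after seeing the data. It also gives the error bars of the plot of named genes and the standard errors printed beside single fold changes. Where 2 effects share the vehicle or control group, the summed variance is conservative.

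The difference test was tested on simulated data in which 200 genes carried a known change. The noise was drawn from the rescaled error, independently for the 2 effects even where they share a group. Few false calls were therefore built in for both errors, and the simulation cannot show which error describes the animals. For high-dose tropifexor against OCA, run on 15206 genes, the implied error recovered 0% of changes of 1 (log2) and 39% of changes of 2, with 0 false calls. The rescaled error recovered 34% and 83%, with 7 false calls. For high against low dose, on 15467 genes, the implied error recovered 0% and 16%, and the rescaled error 21% and 62% with 4 false calls. For the diet effects of the vehicle groups, on 15230 genes, the implied error recovered 1% and 37%, and the rescaled error 41% and 72% with 7 false calls.

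The gene lists, the rule for named genes, the tests and a set of alternatives were fixed before the data were examined. The rule names, for each diet and drug comparison, the 5 largest rises and 5 largest falls among called genes with a group FPKM of at least 1 in one group and 0.1 in the other, leaving out symbols of the Gm and Rik kind. It adds up to 4 called members of each list and 10 genes given in every comparison. Some genes that the rule names are not reported here. Genes named beyond this rule are marked in the text as chosen after their values were seen. There were 27 lists: FXR-induced genes, bile acid synthesis, bile acid uptake, antioxidant and NRF2 targets, extracellular matrix, stellate cells and myofibroblasts, inflammatory mediators, macrophages, lymphocytes and neutrophils, cholangiocytes, endothelial cells, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation, lipid droplets, cholesterol efflux, glucose production, acute phase response, xenobiotic metabolism, endoplasmic reticulum stress, cell cycle, hepatocyte secretory genes, pericentral hepatocytes, periportal hepatocytes, blood cells, pancreas and adipose tissue. Members were matched by symbol. Apoc2 and Itgam were left out because several identifiers share each symbol. For every list the called members were counted, first with the deposited q and then with the deposited p adjusted over the list alone. The median fold change of a list was placed among 10000 random lists of the same size, matched on mean FPKM in 20 bins. This percentile describes these groups and is no p, as genes of a list are not independent and no test that estimates their correlation could be run on group values. It used genes passing the FPKM minimum above, 11880 to 12746 in a table.

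For the opposition of diet and drug effects, the diet effect was taken from the other drug's vehicle group, so that no library was shared. The FPKM minimum was also applied there, a choice made after seeing the data. For pairs of effects that share a reference group, unchanged groups were simulated 100 times against shared reference libraries. This simulation and the correlations and overlaps set beside it were limited to genes with a rescaled standard error under 0.5. The correlations of OCA with tropifexor had the same limit, which was also chosen after seeing the data. Without it, the simulated covariance of the vehicles' diet effects was 1.12, above the observed 0.326, and with it 0.0239 against 0.285. Without the limit, the simulated covariance also exceeded the observed one for low with mid dose (0.660 against 0.305) and low with high dose (0.835 against 0.383), but not for mid with high dose (0.433 against 0.533). The comparisons of mid with low and of high with mid dose, 5 further gene lists, and the use of the other drug's vehicle group were likewise added after seeing the data.

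Coordinates and gene types are those of GENCODE M21 on GRCm38. Of the 47719 identifiers, 47219 were found there. All computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. Other alternatives were a q of 0.01, a minimum of 1.5-fold, an FPKM minimum of 1 with q recomputed, a normal p from the test statistic, centred fold changes, fold changes taken through the tables against lean control, standard errors multiplied by 1.5, and lists drawn or counted in other ways.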

Results

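Gene expression was measured in the liver of 28 male mice in 7 groups of 4. A lean control group ate a low-fat diet with 10% of its calories from fat. The other groups ate a diet with 40% of calories from fat, 22% fructose and 2% cholesterol by weight for 26 weeks, which induces nonalcoholic steatohepatitis (NASH), a fatty liver with inflammation and scarring. They then received daily oral dosing for 4 weeks. Obeticholic acid (OCA), a derivative of a natural bile acid, was given at 25 mg/kg, and tropifexor (LJN452), an agonist without a bile acid structure, at a low dose of 0.1 mg/kg, a mid dose of 0.3 mg/kg and a high dose of 0.9 mg/kg in separate groups, the doses being assigned in rising order because the labels do not pair them with the groups. Both compounds activate FXR, the nuclear receptor that senses bile acids. Each compound had its own vehicle group on the NASH diet, taken from the sample titles although the treatment field of those samples lists the drug. Fold changes, FPKM values and q-values come from the authors' deposited table of each comparison, with 1 value per group of 4, and the depth of each library is unknown.

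The first question was what the NASH diet did to the liver. Genes of scar tissue, inflammation and macrophages were higher in both vehicle groups than in lean control, and genes of cholesterol synthesis were lower. Col1a1, the main chain of type I collagen, rose by 2.71 (log2, rescaled SE 0.193) in the OCA vehicle group and by 3.16 (SE 0.219) in the tropifexor vehicle group, per the authors' deposited table of each. Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 5.76 (SE 0.486) and 6.10 (SE 0.496) in the same order, by the authors' deposited table of each. Sqle, the squalene epoxidase of cholesterol synthesis, fell by 4.33 (SE 0.145) and by 3.95 (SE 0.149) in the authors' deposited table of the same groups. The authors' deposited table of the OCA vehicle group called 2834 genes at a q under 0.05, 1800 higher and 1034 lower, and that of the tropifexor vehicle group 3190, 1869 higher and 1321 lower.

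Of the 24 extracellular matrix genes, 23 rose in each vehicle group and 1 was not called; adjusted over the list alone, 24 rose in each. The authors' deposited table gave Lox, which cross-links collagen, rises of 3.03 and 3.07, and the collagenase Mmp13 rises of 3.58 and 3.54, in the OCA and the tropifexor vehicle groups. Mmp12, the macrophage elastase, rose by 3.88 in both by the authors' deposited table. The gene without a call was Timp1, an inhibitor of matrix proteases, with 3.88 (q = 0.0797) and 4.04 (q = 0.0507) in the authors' deposited table; its locus overlaps another gene, so its value is uncertain. Among 13 genes of stellate cells and myofibroblasts, the cells that make scar matrix, 5 rose and 8 were not called in each vehicle group, with the same counts when adjusted over the list alone. Vim, an intermediate filament, rose by 0.98 and 1.09 in the authors' deposited table, while Acta2, smooth muscle actin, stood at 0.02 and -0.05. Of 12 cell cycle genes, 10 were tested in the OCA vehicle group, where 9 rose, and 12 in the tropifexor vehicle group, where 11 rose, with the same counts adjusted over the list alone. Top2a, a topoisomerase of dividing cells, rose by 2.40 and 2.78 by the authors' deposited table.

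Of the 20 inflammatory mediators, 19 were tested; 15 rose and 4 were not called in each vehicle group, and adjusted over the list alone 18 rose in the OCA and 15 in the tropifexor vehicle group. Per the authors' deposited table, Ccl2, a chemokine that attracts monocytes, rose by 1.94 (SE 0.201) and 2.05 (SE 0.214), and its receptor Ccr2 by 2.31 and 2.56. Of 17 macrophage genes 16 were tested; 13 rose, 1 fell and 2 were not called in the OCA vehicle group, and 12 rose, 1 fell and 3 were not called in the tropifexor vehicle group. Adjusted over the list alone, 14 and 12 macrophage genes rose and 1 fell in each. Trem2, a lipid receptor of macrophages, rose by 3.24 and 3.55 in the authors' deposited table, and Timd4, a marker of resident Kupffer cells, fell by 0.63 and by 0.86. Of 13 genes of lymphocytes and neutrophils, 11 were tested and 5 rose in the OCA vehicle group (6 adjusted over the list alone), and 10 were tested and 4 rose in the tropifexor vehicle group (4 adjusted over the list alone). The authors' deposited table gave Cd8a, of cytotoxic T cells, rises of 2.33 and 1.68. In the acute phase response, a list of 14, 7 and 8 rose and 1 fell in each; adjusted over the list alone, 7 rose and 1 fell, and 8 rose and 2 fell. Lcn2, lipocalin 2, rose by 3.26 and 3.39 by the authors' deposited table; Saa1, Saa2 and the Orm genes on this list are close paralogs and uncertain.

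Of 19 cholesterol synthesis genes, 16 fell and 3 were not called in each vehicle group, also when adjusted over the list alone. By the authors' deposited table Fdps, which makes farnesyl diphosphate, fell by 2.61 and by 2.24, and Cyp51, lanosterol demethylase, fell by 2.49 and by 2.22. Of 14 fatty acid synthesis genes, 2 rose and 6 fell in the OCA vehicle group and 1 rose and 8 fell in the tropifexor vehicle group; adjusted over the list alone, 2 rose and 7 fell, and 1 rose and 11 fell. Srebf1, the transcription factor of this pathway, rose by 0.98 in the OCA vehicle group and stood at 0.09 (q = 0.904) in the tropifexor vehicle group, per the authors' deposited table. Of 12 lipid droplet genes 11 were tested, and 7 and 9 rose, with the same counts adjusted over the list alone. Cidea, a droplet fusion protein, rose by 4.02 and 4.50 and the related Cidec by 4.03 and 4.46 in the authors' deposited table. Of 8 cholesterol efflux genes, 4 rose in the OCA vehicle group (5 adjusted over the list alone) and 2 in the tropifexor vehicle group (2 adjusted over the list alone). Abcg5, a sterol exporter, rose by 1.36 and 0.85 per the authors' deposited table. Of 17 fatty acid oxidation genes, 2 rose and 3 fell in each group; adjusted over the list alone, 2 rose and 3 fell, and 2 rose and 4 fell. Of 8 genes of glucose production, 2 and 3 fell, with the same counts adjusted over the list alone.

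Bile acid genes moved in both directions with the diet. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 2.27 (SE 0.413) and 2.42 (SE 0.425), and Cyp8b1, which sets the share of cholic acid, fell by 1.62 (SE 0.140) and by 1.17 (SE 0.134), by the authors' deposited table. Of 14 bile acid synthesis genes, 1 rose and 4 fell in the OCA vehicle group and 2 rose and 5 fell in the tropifexor vehicle group; adjusted over the list alone, 1 rose and 4 fell, and 2 rose and 6 fell. Of 5 bile acid uptake genes, 3 and 4 fell (3 and 5 adjusted over the list alone), with the transporter Slc10a1 at -1.64 and -1.86 in the authors' deposited table. Of 18 FXR-induced genes 16 were tested: 2 rose in the OCA vehicle group, and 1 rose and 6 fell in the tropifexor vehicle group. Adjusted over the list alone, 2 rose, and 3 rose and 7 fell. Nr0b2, the FXR-induced repressor SHP, was at -0.08 (q = 0.803) and -0.61 (q = 0.000507), and Abcb11, the bile salt export pump, at -0.51 (q = 0.156) and -0.47 (q = 0.237) in the authors' deposited table. Slc51b, an exporter of bile acids, stood at 1.03 (q = 0.00982) and 0.87 (q = 0.0535) in the authors' deposited table.

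Among 28 antioxidant genes and NRF2 targets 27 were tested, and 13 rose in the OCA vehicle group, and 12 rose and 1 fell in the tropifexor vehicle group; adjusted over the list alone, 13 rose and 1 fell, and 12 rose and 2 fell. Nqo1, a quinone reductase, rose by 0.82 (SE 0.136) and 0.79 (SE 0.148), and Cbr3, a carbonyl reductase, by 1.89 and 1.98 in the authors' deposited table; the Gst genes of this list are paralogs and uncertain. Of the 16 xenobiotic genes, 7 rose and 1 fell in the OCA vehicle group, and of 15 tested in the tropifexor vehicle group 5 rose and 5 fell, with the same counts adjusted over the list alone. Por, the electron donor of cytochrome P450 enzymes, rose by 1.06 and 0.90 by the authors' deposited table. Of 14 genes of endoplasmic reticulum stress, 2 rose and 1 fell, and 2 rose and 2 fell; adjusted over the list alone, 2 rose and 2 fell in each. Of 11 hepatocyte secretory genes, 2 fell in the OCA vehicle group and 5 in the tropifexor vehicle group (2 and 6 adjusted over the list alone). Of 8 pericentral hepatocyte genes, 0 and 1 were called, also when adjusted over the list alone, and in the OCA vehicle group the authors' Cuffdiff test gave 1 of them an unadjusted p under 0.05. Of 8 periportal genes, 3 and 6 fell (5 and 6 adjusted over the list alone), among them Ass1 of the urea cycle with -0.84 and -0.79 in the authors' deposited table.

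Markers of other cells moved beside these groups. Of 6 blood cell genes, 4 fell in the OCA vehicle group and 5 in the tropifexor vehicle group, also when adjusted over the list alone, with a median of -0.54 and -0.82; 4 of them are globin paralogs and uncertain. Of 7 endothelial genes 2 fell in each, also when adjusted over the list alone. Of 7 cholangiocyte genes 6 were tested, and 2 rose and 1 fell in each; adjusted over the list alone, 3 rose and 1 fell, and 2 rose and 2 fell. Of 7 pancreas genes 2 were tested and 0 were called by the authors' Cuffdiff test, with 1 and 0 at an unadjusted p under 0.05, and 1 and 0 lower when adjusted over the list alone. Of 5 adipose genes 1 was tested, Cfd (adipsin), which rose by 5.12 and 4.57 by the authors' deposited table, with the same calls adjusted over the list alone.

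The 5 largest rises were the same genes in both vehicle groups: Gpnmb, Cfd, the scaffold protein Sdcbp2 with 4.71 and 5.17, the estrogen sulfotransferase Sult1e1 with 4.30 and 5.16, and the trypsin inhibitor Spink1 with 4.23 and 5.05, in the authors' deposited table. Besides Sqle, the largest falls included Zfp618 with -3.84 and -4.23, the acetylcholine receptor subunit Chrna4 with -3.71 and -3.31 and the receptor Adgrf1 with -2.96 and -3.37, per the authors' deposited table. The trefoil factor Tff3 was among them in the OCA vehicle group with -2.80, and the steroid dehydrogenase Hsd3b5 in the tropifexor vehicle group with -3.53, by the authors' deposited table. Across 7 comparisons of fold changes, the difference of the diet effects between the vehicle groups was called (normal test of the difference, Benjamini-Hochberg) for 15 genes, 8 higher and 7 lower in the tropifexor vehicle group. Over the 10655 genes with a rescaled standard error under 0.5 in both, the fold changes correlated with r = 0.935. Unchanged groups sharing the lean controls gave 0.502, and the covariance was 0.285 against 0.0239. Without that limit, chosen after seeing the data, the simulated covariance of 1.12 exceeded the observed 0.326. Among the 10655 genes, the OCA and tropifexor vehicle groups called 1286 and 1352 higher and 928 and 1188 lower. Both called 1118 of these genes higher (163 for independent lists) and 778 lower (103), and 6 in opposite directions. Genes are not independent replicates, and part of the overlap may come from the shared controls, which cannot be split.

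The second question was what OCA changed on the NASH diet. Of the tested genes, 7 of 16 macrophage genes and 4 of 19 inflammatory mediators fell, 7 of 18 cholesterol synthesis genes rose and of 24 matrix genes 2 rose and 1 fell; adjusted over the list alone, 12 macrophage genes and 9 mediators fell, 12 cholesterol synthesis genes rose, and 2 matrix genes rose and 2 fell. The median lay above 0% of random lists for macrophage genes (-0.45) and inflammatory mediators (-0.30), above 100% for cholesterol synthesis (0.71) and above 7.80% for matrix genes (-0.08). Slc51b rose by 2.72 (SE 0.220) and Nr0b2 by 0.75 (SE 0.129), while Cyp8b1 fell by 2.95 (SE 0.133) and Cyp7a1 fell by 1.49 (SE 0.414), per the authors' deposited table. Col1a1 stood at 0.02 (SE 0.211, q = 0.999) and Ccl2 at 0.03 (SE 0.169, q = 0.999) in the authors' deposited table. That table, the authors' deposited table of OCA against its vehicle, called 634 genes, 284 higher and 350 lower.

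Of the 16 tested FXR-induced genes, 3 rose and 13 were not called under OCA, also when adjusted over the list alone; the third was Akr1b7, an aldo-keto reductase, with 1.64 in the authors' deposited table. Abcb11 was at 0.76 (q = 0.229) in the authors' deposited table. Of bile acid synthesis genes 2 rose and 3 fell, and of uptake genes 1 fell, also when adjusted over the list alone; Cyp7b1, of the alternative synthesis pathway, fell by 1.01, and Akr1d1, a steroid reductase, rose by 0.76 per the authors' deposited table. Cholesterol synthesis had 18 tested genes, of which 7 rose and 11 were not called; adjusted over the list alone, 12 rose. Sqle rose by 1.28 by the authors' deposited table. Of fatty acid synthesis genes 2 rose, and of lipid droplet genes 2 fell, also when adjusted over the list alone, among the latter Cidea with -1.92 in the authors' deposited table.

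Of 16 tested macrophage genes, 7 fell and 9 were not called, and adjusted over the list alone 12 fell. Timd4 was lower at -1.16, the complement receptor Vsig4 at -0.91 and the macrophage marker Adgre1 at -0.78 in the authors' deposited table. Of 19 inflammatory mediators, 4 fell (9 adjusted over the list alone), and the chemokines Ccl5, Ccl4 and Ccl3 were at -1.39, -1.04 and -0.89 in the authors' deposited table. Of 11 tested genes of lymphocytes and neutrophils 3 fell (4 adjusted over the list alone), with the granule gene Nkg7 at -1.37 per the authors' deposited table. Of 24 matrix genes, 2 rose and 1 fell (2 and 2 adjusted over the list alone), and Spp1, osteopontin, rose by 0.61 by the authors' deposited table. Of 13 stellate cell genes 0 were called by the authors' Cuffdiff test, also when adjusted over the list alone, and 2 had an unadjusted p under 0.05. Timp1 stood at -0.19, Nqo1 at 0.16 and Srebf1 at -0.66, none called in the authors' deposited table.

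In the remaining lists, 5 antioxidant genes rose and 2 fell and 4 acute phase genes fell, with the same counts adjusted over the list alone. Of xenobiotic genes 1 rose and 4 fell (1 and 7 adjusted over the list alone), and of endoplasmic reticulum stress genes 1 rose and 3 fell (2 and 4 adjusted over the list alone). Of fatty acid oxidation genes 2 fell (1 rose and 3 fell adjusted over the list alone), of cholesterol efflux genes 1 fell and of glucose production genes 2 rose and 1 fell, the last 2 lists also when adjusted over the list alone. G6pc, glucose-6-phosphatase, fell by 1.89 in the authors' deposited table. Of periportal genes 3 rose (5 adjusted over the list alone), with Ass1 at 0.81 in the authors' deposited table. Of cell cycle genes 2 rose, of endothelial genes 2 fell and of cholangiocyte genes 1 rose, all also when adjusted over the list alone. Of pericentral, hepatocyte secretory and blood cell genes 0 were called by the authors' Cuffdiff test, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone in each. Of pancreas genes 1 was tested under OCA and 0 were called, with 0 at an unadjusted p under 0.05, and the adipose gene Cfd fell.

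Among the largest rises under OCA besides Slc51b were Ptgds, a prostaglandin D2 synthase, with 3.42, the cytokine signalling inhibitor Cish with 2.34 and the liver transcription factor Onecut1 with 2.29, in the authors' deposited table. Against lean control, the OCA vehicle group itself was at -1.41 for Cish and -1.57 for Onecut1 and the tropifexor vehicle group at 1.09 and 0.85, per the authors' deposited table. The largest falls were Serpina1e with -4.80, Mup11 with -4.46, Cfd with -4.18, Mup17 with -3.20 and Mup14 with -2.97 by the authors' deposited table; the Serpina1 and Mup genes belong to families of near-identical copies and are uncertain. Taken through the tables against lean control with the rescaled error, chosen like the other vehicle group after seeing the data, OCA called 211 genes against its own vehicle group, 111 higher and 100 lower, and 241 against the other, 146 higher and 95 lower, where Cish stood at -0.15 and Onecut1 at -0.13. Of 628 genes called against its own vehicle, 601 had the same sign against the other and 161 were called again. The same route with its own vehicle kept 180 calls in the same direction, as its summed variance counts the lean control 2 times.

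The third question was what tropifexor changed at each dose. At the mid and high doses most tested matrix (22 and 21 of 24), stellate cell (10 and 11 of 13), inflammatory (17 and 16 of 19) and macrophage genes (14 and 11 of 16) fell. Of the 19 cholesterol synthesis genes 13, 17 and 16 rose at the low, mid and high doses, and of 16 FXR-induced genes 6, 8 and 9 rose and 1 fell at the high dose. Col1a1 fell by 1.52 (SE 0.306) at the low, by 3.03 (SE 0.183) at the mid and by 2.70 (SE 0.168) at the high dose, per the authors' deposited table of each. Ccl2 rose by 0.88 (SE 0.233) at the low dose and fell by 1.62 (SE 0.207) and by 1.58 (SE 0.210) at the mid and high doses, by the authors' deposited table of each. Ptgds rose by 7.43 (SE 0.321), 10.35 (SE 0.227) and 11.36 (SE 0.243), at the high dose from an FPKM of 3.53 in vehicle to 9252, in the authors' deposited table. The authors' deposited table called 1813 genes at the low dose, 973 higher and 840 lower, and 4319 at the mid dose, 1849 higher and 2470 lower. At the high dose it called 4015, 1570 higher and 2445 lower. The median rescaled standard error was 0.265 at the low dose against 0.198 at the mid and high doses. Fewer calls at the low dose therefore do not by themselves show smaller effects. Through the tables against lean control with the rescaled error, the low dose had 466 genes higher and 520 lower against its own vehicle group, and 502 higher and 574 lower against the other.

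Of the 16 tested FXR-induced genes, 6, 8 and 9 rose at the low, mid and high doses and 0, 0 and 1 fell; adjusted over the list alone, 6, 10 and 9 rose and 0, 0 and 1 fell. Nr0b2 rose by 1.87 (SE 0.175), 2.55 (SE 0.130) and 2.63 (SE 0.128), and Slc51b by 5.38 (SE 0.318), 6.01 (SE 0.249) and 6.08 (SE 0.256) in the authors' deposited table. Abcb11 was at 0.90 (q = 0.154) at the low dose and rose by 2.18 and 2.14 at the mid and high doses, per the authors' deposited table. Osgin1, an oxidative stress-induced growth inhibitor, rose by 2.56, 2.83 and 3.41 by the authors' deposited table. Of 14 bile acid synthesis genes, 2, 6 and 4 rose and 6, 4 and 6 fell; adjusted over the list alone, 2, 7 and 4 rose and 6, 5 and 6 fell. Cyp7a1 fell by 4.17 (SE 0.512), by 3.24 (SE 0.464) and by 6.03 (SE 1.05), and Cyp8b1 fell by 6.68 (SE 0.292), by 5.04 (SE 0.169) and by 8.55 (SE 0.251) in the authors' deposited table. Akr1d1 rose by 0.99, 2.12 and 1.88 per the authors' deposited table. Of 5 uptake genes, 0, 3 and 0 rose and 2, 1 and 2 fell; adjusted over the list alone, 1, 3 and 1 rose and 4, 1 and 2 fell. The organic anion transporter Slco1a1 fell by 4.48, by 2.90 and by 6.35, and Slc10a1 was at -1.53, 0.23 and -3.35, not called at the mid dose, in the authors' deposited table.

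**Figure D1:**
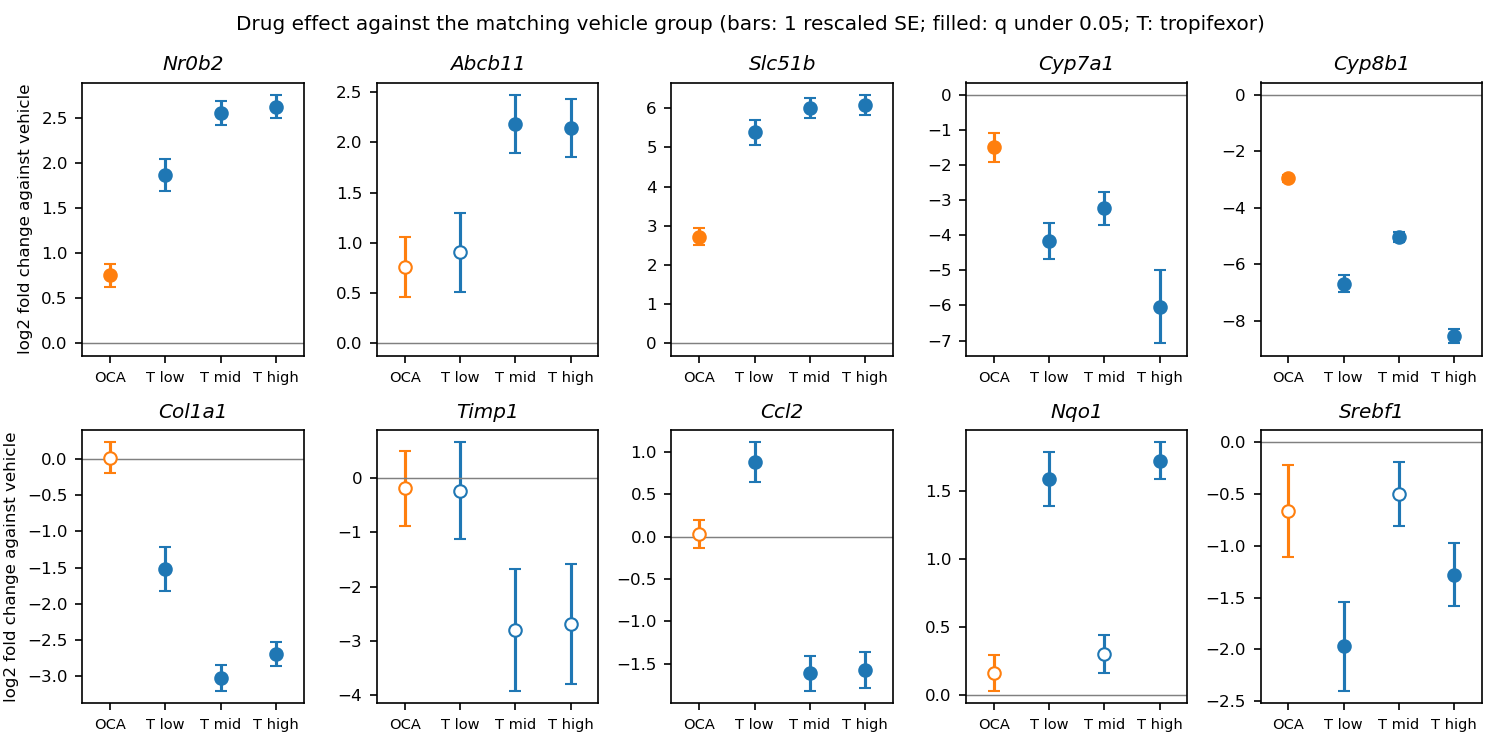
Log2 fold change of the genes given in every comparison, for OCA and the 3 tropifexor doses against their vehicles. Bars are 1 rescaled standard error, the deposited fold change over its test statistic divided by the table's median ratio of normal z to statistic. Cyp8b1 reached -8.55 at the high tropifexor dose, and Col1a1 stood at 0.02 under OCA and at -3.03 at the mid tropifexor dose.

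Of 24 matrix genes, 3, 0 and 1 rose and 10, 22 and 21 fell at the low, mid and high doses; adjusted over the list alone, 4, 1 and 1 rose and 12, 22 and 22 fell. The collagen Col3a1 fell by 1.69, by 2.68 and by 2.62, and Lox fell by 0.98, by 2.95 and by 2.47, by the authors' deposited table. Mmp13 rose by 0.77 at the low dose and fell by 2.86 and by 2.99 at the mid and high doses in the authors' deposited table. Timp1 was at -0.23, -2.80 and -2.69 and not called (q = 0.966, 0.186 and 0.319) in the authors' deposited table. Of 13 stellate cell genes, 0, 1 and 1 rose and 3, 10 and 11 fell, also when adjusted over the list alone. Acta2 fell by 0.86, by 1.16 and by 1.46 per the authors' deposited table. The gene that rose was Lhx2, a transcription factor, with 1.19 and 1.08 at the mid and high doses, in the authors' deposited table.

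Of 19 inflammatory mediators, 3 rose at the low dose and 17 and 16 fell at the mid and high doses; adjusted over the list alone, 3 rose, and 19 and 17 fell. The neutrophil chemokine Cxcl1 fell by 2.07 and by 2.03 at the mid and high doses, and was at -0.57 without a call at the low dose, by the authors' deposited table. The toll-like receptor Tlr2 rose by 0.68 and then fell by 1.20 and by 0.65 in the authors' deposited table. Of 16 macrophage genes, 1, 14 and 11 fell; adjusted over the list alone, 1, 14 and 12 fell. Gpnmb was at -0.30 (q = 0.427) at the low dose and fell by 2.96 and by 2.38 at the mid and high doses, and Mpeg1, perforin 2, fell by 0.58, by 1.42 and by 1.80, per the authors' deposited table. Of genes of lymphocytes and neutrophils 12, 10 and 11 were tested and 0, 6 and 4 fell, also when adjusted over the list alone, and at the low dose the authors' Cuffdiff test gave 2 an unadjusted p under 0.05. Of 14 acute phase genes, 1 rose at each dose and 3, 10 and 12 fell; adjusted over the list alone, 1 rose at each dose and 4, 11 and 12 fell. Fgl1, a fibrinogen-like hepatokine, fell by 1.91, by 3.82 and by 5.50 in the authors' deposited table. Beside these groups, 4 of 7 cholangiocyte genes rose at the low dose (5 adjusted over the list alone), with Epcam at 1.63 in the authors' deposited table, and 2 and 1 of 6 fell at the mid and high doses, also when adjusted over the list alone. Of 7 endothelial genes 1, 4 and 4 fell (2, 4 and 4 adjusted over the list alone). Of 6 blood cell genes 1 fell at the low dose, 1 rose at the mid dose and 0 were called at the high dose, also when adjusted over the list alone; at the high dose 1 had an unadjusted p under 0.05 in the authors' Cuffdiff test.

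Of 19 cholesterol synthesis genes, 13, 17 and 16 rose; adjusted over the list alone, 13, 17 and 16 rose and 0, 0 and 1 fell. Sqle rose by 3.77 (SE 0.209), 4.23 (SE 0.156) and 4.00 (SE 0.162), by the authors' deposited table. Of 14 fatty acid synthesis genes, 0, 5 and 2 rose and 7, 2 and 6 fell; adjusted over the list alone, 1, 6 and 2 rose and 7, 2 and 6 fell. Srebf1 fell by 1.97 (SE 0.431) and by 1.28 (SE 0.307) at the low and high doses and stood at -0.50 (q = 0.196) at the mid dose, in the authors' deposited table. Thrsp, a lipogenic regulator, rose by 2.90 and 1.32 at the mid and high doses per the authors' deposited table. Of 11 lipid droplet genes, 1 rose at each dose and 5, 4 and 7 fell; adjusted over the list alone, 2, 2 and 1 rose and 5, 4 and 8 fell. Mogat1, an acyltransferase, fell by 3.64, by 4.00 and by 4.03, by the authors' deposited table. Cidea stood at -5.72, -9.17 and -8.43 in the authors' deposited table, without a call at the mid dose. Of 17 fatty acid oxidation genes, 1, 3 and 2 rose and 7, 7 and 8 fell; adjusted over the list alone, 2, 3 and 2 rose and 7, 7 and 8 fell. Fgf21, a fasting hormone, rose by 3.24, 1.94 and 2.79, and Cyp4a14, a fatty acid hydroxylase, fell by 0.73, by 3.70 and by 3.68 in the authors' deposited table. Of 8 cholesterol efflux genes, 1, 2 and 2 fell (3, 2 and 2 adjusted over the list alone). Of 8 glucose production genes, 2, 3 and 1 rose and 2, 2 and 3 fell; adjusted over the list alone, 2, 4 and 1 rose and 2, 2 and 3 fell. Igfbp1, which binds insulin-like growth factors, rose at the low dose and fell by 2.14 and by 2.21 at the mid and high doses, per the authors' deposited table.

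Antioxidant genes were tested for 28, 27 and 27 members, of which 9, 10 and 15 rose and 1, 4 and 3 fell; adjusted over the list alone, 9, 11 and 16 rose and 1, 5 and 3 fell. Nqo1 rose by 1.59 (SE 0.198) and 1.72 (SE 0.136) at the low and high doses and stood at 0.30 (q = 0.108) at the mid dose, and Cbr3 was at 3.67, 2.21 and -0.14 for low, high and mid, in the authors' deposited table. Of xenobiotic genes 16, 15 and 15 were tested, 3, 4 and 4 rose and 5, 8 and 6 fell; adjusted over the list alone, 3, 4 and 4 rose and 7, 8 and 6 fell. Cyp2e1, which oxidises ethanol, fell by 1.61, by 1.59 and by 1.90, by the authors' deposited table, while the Cyp2b and Cyp2c genes on the list are paralogs and uncertain. Of 14 endoplasmic reticulum stress genes, 4, 3 and 5 rose and 2, 6 and 5 fell; adjusted over the list alone, 4, 4 and 5 rose and 2, 6 and 5 fell. Trib3, a pseudokinase of the stress response, rose by 2.26, 1.06 and 1.82 in the authors' deposited table. Of 12 cell cycle genes, 1 rose at each dose and 0, 8 and 7 fell; adjusted over the list alone, 1 rose and 0, 9 and 9 fell. The gene that rose was Ccnd1, cyclin D1, with 1.90, 1.95 and 2.07 in the authors' deposited table. Of 8 pericentral genes, 6 fell at each dose (8, 6 and 7 adjusted over the list alone), among them Glul, glutamine synthetase, with -1.86, -0.71 and -1.53 in the authors' deposited table. Of 8 periportal genes, 1, 8 and 7 rose (3, 8 and 7 adjusted over the list alone); Hal, histidine ammonia-lyase, rose by 0.95, 2.13 and 1.64 per the authors' deposited table. Of 11 hepatocyte secretory genes 0, 1 and 1 rose and 1, 1 and 2 fell, also when adjusted over the list alone. Of pancreas genes 2, 1 and 1 were tested and 0 were called by the authors' Cuffdiff test, with 0 at an unadjusted p under 0.05.

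**Figure D2:**
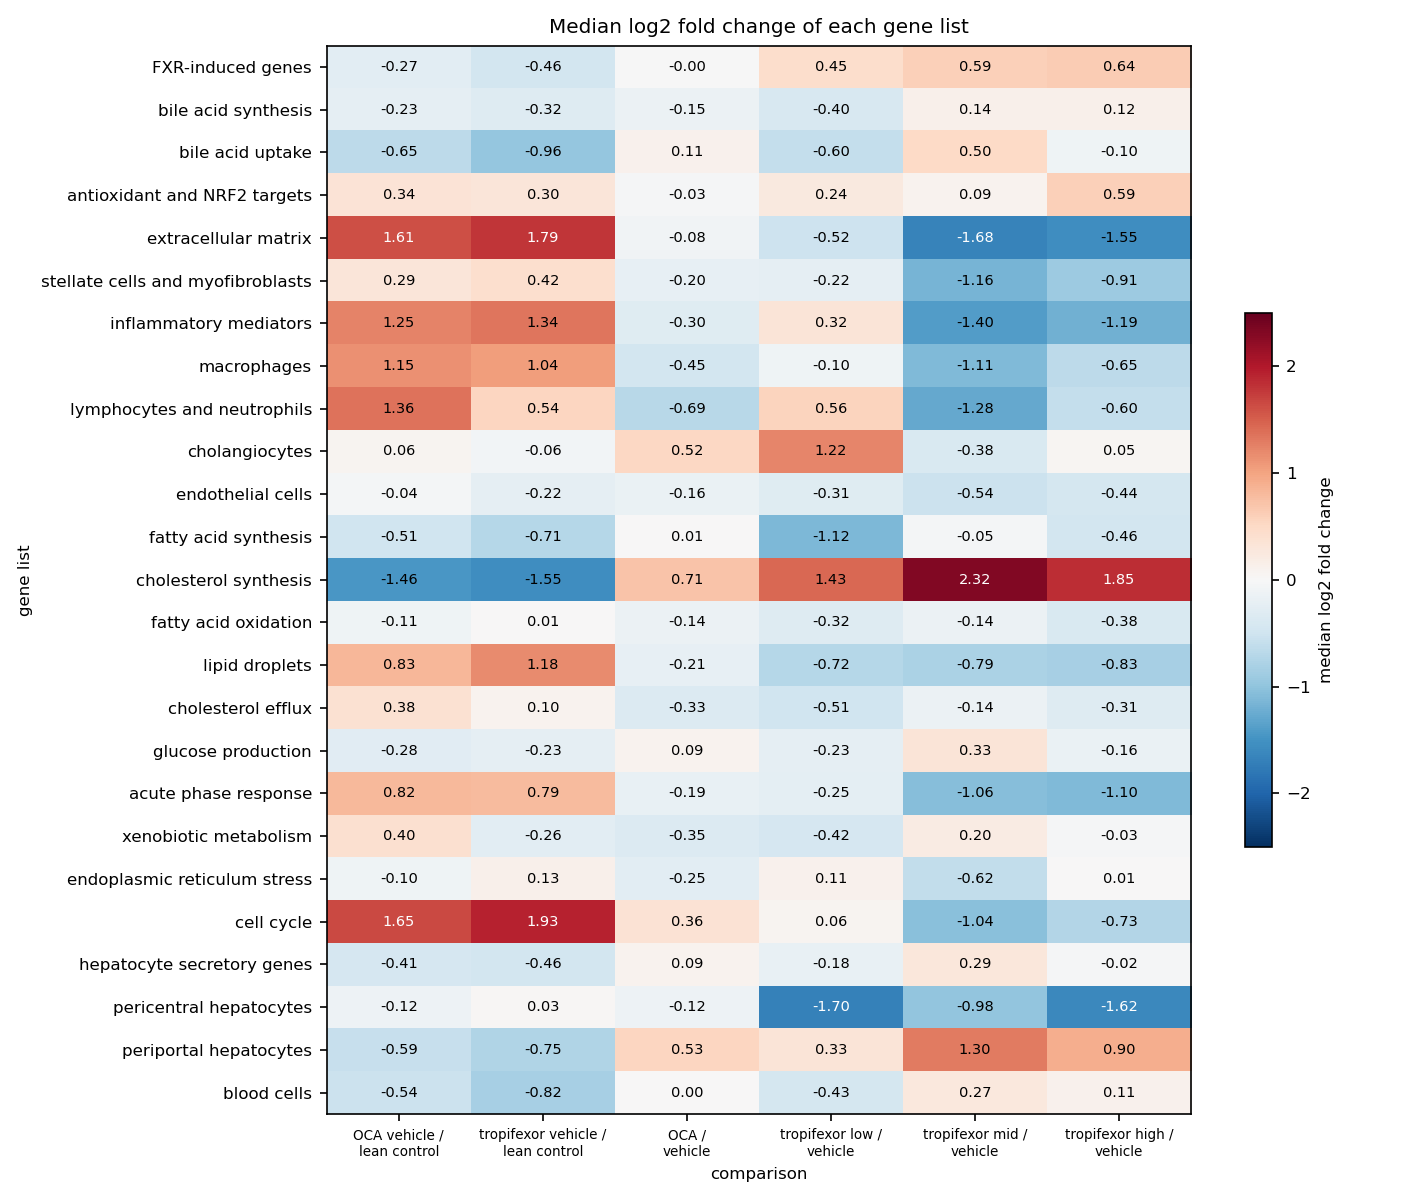
Median log2 fold change of the members of each gene list in the diet and drug comparisons. The extracellular matrix median was 1.61 and 1.79 with the diet, -0.08 under OCA and -0.52, -1.68 and -1.55 at the low, mid and high tropifexor doses.

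Other genes among the largest rises were the imprinted RNA H19 with 5.91 at the low dose, the chloride channel protein Clic3 with 5.87, 7.67 and 7.20 and Akr1b7 with 5.55, 5.80 and 7.54, in the authors' deposited table. The serine protease Tmprss4 at the mid dose had 6.18, and Fcnaos, an antisense gene and therefore uncertain, 6.36 at the high dose by the authors' deposited table. The largest falls included Cfd with -6.95 and Mup17 with -6.59 at the low dose, Mup11 with -8.62 and -6.64 at the low and mid doses, and Serpina4-ps1 with -6.72, -6.09 and -7.09, per the authors' deposited table, the latter 3 being uncertain paralogs. Serpina1e, also a paralog, with -4.87 and Sdcbp2 with -4.82 followed at the mid dose and the membrane receptor Paqr9 with -6.08 at the high dose, in the authors' deposited table. The fold changes of the doses share 1 vehicle group, and their correlations use genes with a rescaled standard error under 0.5 in both doses. Across 10643 such genes the mid and high doses correlated with r = 0.876 (0.499 for unchanged groups, covariance 0.465 against 0.0252). Low correlated with mid at 0.588 across 10123 genes (0.504 for unchanged groups, covariance 0.248 against 0.0295). Low correlated with high at 0.724 (0.504 for unchanged groups, covariance 0.322 against 0.0296). Without the limit on the standard error, chosen after seeing the data, the simulated covariance exceeded the observed one for both low-dose pairs. It was 0.660 against 0.305 for low with mid and 0.835 against 0.383 for low with high. Among the 10643 genes of the mid and high comparison, these doses called 1663 and 1359 higher and 1769 and 1916 lower. Both called 1101 of these genes higher (212 for independent lists) and 1379 lower (318). Part of these overlaps may come from the shared vehicle group, and genes are not independent replicates.

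Among the tropifexor doses, changes were tested directly, by the difference of their fold changes with a normal 95% interval. Ccl2 was lower at the high than at the low dose by a difference of -2.45 (95% interval -3.71 to -1.20), and H19 by -3.72, both called after Benjamini-Hochberg adjustment. Between mid and low dose, Ccl2 differed by -2.49 (-3.74 to -1.25) and Gpnmb by -2.66, both called. Cyp8b1 was lower at the high than at the mid dose by -3.51, which was called, while a difference of 1.42 for Nqo1 was not called with the implied error. In all, 43 genes differed between high and low, 11 higher and 32 lower, 65 between mid and low, 12 higher and 53 lower, and 49 between high and mid, 16 higher and 33 lower. Of 19 inflammatory mediators, 1 was lower at high and 2 at mid than at low dose, and 14 and 15 with the rescaled error. With that error, chosen after seeing the data, the gene counts were 870, 1575 and 357.

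The fourth question was how the compounds compared. Their doses differ and are not matched, so values stand side by side. At the high tropifexor dose of 0.9 mg/kg, Cyp8b1 was lower than with OCA at 25 mg/kg by a difference of fold changes of -5.59 (95% interval -6.72 to -4.46), and Col1a1 by -2.73 (-3.80 to -1.65). Nr0b2 was higher by 1.87 (1.15 to 2.60), Slc51b by 3.36 (2.01 to 4.70), Sqle by 2.72 (1.82 to 3.62) and Nqo1 by 1.56 (0.80 to 2.32). Ptgds was higher by 7.94 (6.69 to 9.19) and Akr1b7 by 5.90 (4.61 to 7.19). All of these were called by the normal test of the difference after Benjamini-Hochberg adjustment. The difference was not called for Ccl2 with -1.61 (-2.68 to -0.54), Cyp7a1 with -4.54 (-9.04 to -0.04) and Abcb11 with 1.38 (-0.26 to 3.02). Nor was it called for Srebf1 with -0.61 (-2.77 to 1.54) and Timp1 with -2.51 (-7.69 to 2.68). These intervals and calls use the implied error, about 2 times as wide as the deposited p assumes. A missing call therefore does not show that the effects were alike.

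In the mid dose comparison with OCA, Col1a1 was lower by -3.05 (-4.16 to -1.94), Gpnmb lower by -2.69 (-3.78 to -1.59) and Slc51b higher by 3.29 (1.97 to 4.61), all called. At the low dose Cyp8b1 was lower by -3.73 (-5.01 to -2.44), which was called, while Nr0b2 with 1.11 (0.24 to 1.98) and Slc51b with 2.66 (1.11 to 4.21) were not. These too rest on the wide implied error. Of 24 matrix genes, 14 were lower at the mid and 10 at the high dose than with OCA, and of 16 FXR-induced genes 4 were higher at each of these doses. Of 18 cholesterol synthesis genes, 4 and 3 were higher, and of 19 inflammatory mediators 2 and 2 were lower. With the rescaled error, 21 and 20 matrix genes and 7 and 5 inflammatory mediators were lower at the mid and high doses. With that error 7 and 7 FXR-induced and 12 and 10 cholesterol synthesis genes were higher. At the low dose 17 mediators lay above and 2 below OCA, with a median difference of 0.846. None of them was called, while 2 FXR-induced genes and 1 cholesterol synthesis gene were higher and 0 matrix genes were called. With the rescaled error 4 mediators, 4 FXR-induced and 6 cholesterol synthesis genes were higher at the low dose. Of matrix genes 2 were then higher and 8 lower. In total, 64 genes differed between low dose and OCA, 35 higher and 29 lower; 225 between mid dose and OCA, 100 higher and 125 lower; and 257 between high dose and OCA, 114 higher and 143 lower. With the rescaled error, chosen after seeing the data, the counts were 797, 1821 and 1739. OCA and tropifexor share no libraries. Over genes with a rescaled standard error under 0.5 in both, their fold changes correlated at 0.485, 0.572 and 0.522 for the low, mid and high doses. Genes are not independent replicates.

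The fifth question was how far drug effects ran against the diet effect. The diet effect was taken from the other drug's vehicle group, so that no library was shared. At the mid tropifexor dose, 846 of 1317 genes that rose with the diet were called lower (64.2%), and at the high dose 717 of 1323 (54.2%); at the low dose it was 143 of 1343 and with OCA 163 of 1407. Of genes that fell with the diet, 371 of 896 were called higher at the mid dose (41.4%), 244 of 893 at the high dose (27.3%), where 205 were called lower again (23.0%), 131 of 904 at the low dose and 94 of 1157 with OCA. Of all genes called for the diet, 55.0% were called in the opposite direction at the mid dose and 10.5% in the same. The shares were 43.4% and 16.7% at the high dose, 12.2% and 15.0% at the low dose, and 10.0% and 4.17% with OCA. Genes not called for the diet were called lower in 8.73%, 10.6%, 4.59% and 0.868% at the mid, high and low doses and with OCA. They were called higher in 11.5%, 9.37%, 3.77% and 0.932%. Opposite calls were 3.79, 3.06, 2.04 and 4.46 times those of independent lists, so the shares above depend on how many genes each drug called. This ratio was not computed for calls in the same direction. At the low dose 274 genes were called in the opposite and 336 in the same direction, so its ratio of 2.04 does not show that effects ran against the diet. Fold changes of diet and drug correlated across genes at -0.418, -0.241, 0.0013 and -0.184 in that order; genes are not independent replicates. With each drug's own vehicle group in both effects, which then share libraries, r was -0.388 for OCA and -0.108 for the low dose.

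**Figure D3:**
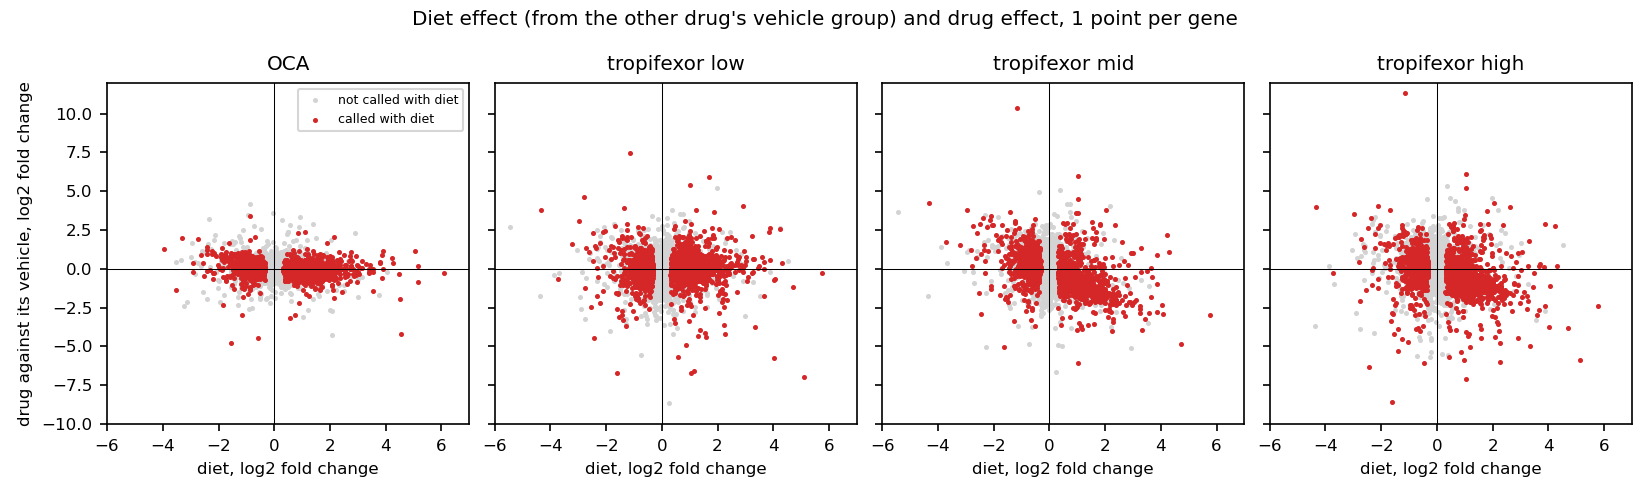
Log2 fold change of each drug group against its vehicle, plotted over the log2 fold change of the diet in the other drug's vehicle group, 1 point per gene. At the mid tropifexor dose the correlation across genes was -0.418, and at the low dose 0.0013.

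The last comparisons set the treated animals against lean control. Gpnmb was higher than in lean control by 5.49 with OCA and by 5.80, 3.13 and 3.70 at the low, mid and high tropifexor doses, in the authors' deposited table. Col1a1 was higher by 2.74 with OCA, 1.64 at the low and 0.45 at the high dose, and stood at 0.13 (q = 0.678) at the mid dose by the authors' deposited table. Ccl2 was at 1.98, 2.92, 0.43 and 0.46 for OCA and the low, mid and high doses, not called at the mid and high doses, per the authors' deposited table. Sqle was lower with OCA, at -3.04, and not called at any tropifexor dose, with -0.17, 0.28 and 0.04 in the authors' deposited table. Cyp8b1 was at -4.57, -7.85, -6.22 and -9.73, all called, in the authors' deposited table. The authors' deposited table called 2549 genes for OCA, 3796 for the low, 3523 for the mid and 4222 for the high dose.

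In mouse build GRCm38, Nr0b2 (ENSMUSG00000037583) lies on chromosome 4 from 133553376 to 133556536, Cyp7a1 (ENSMUSG00000028240) on chromosome 4 from 6265612 to 6275633 and Cyp8b1 (ENSMUSG00000050445) on chromosome 9 from 121914356 to 121916305. Slc51b (ENSMUSG00000053862) lies on chromosome 9 from 65412714 to 65422955, and Abcb11 (ENSMUSG00000027048) on chromosome 2 from 69238282 to 69342616. Col1a1 (ENSMUSG00000001506) spans 94936224 to 94953042, Ccl2 (ENSMUSG00000035385) 82035571 to 82037453 and Srebf1 (ENSMUSG00000020538) 60199089 to 60222581, all on chromosome 11. Timp1 (ENSMUSG00000001131) spans 20870166 to 20874735 of chromosome X, and Nqo1 (ENSMUSG00000003849) 107388225 to 107403206 of chromosome 8. Sqle (ENSMUSG00000022351) lies on chromosome 15 from 59315077 to 59331192, Ptgds (ENSMUSG00000015090) on chromosome 2 from 25466709 to 25470046 and Gpnmb (ENSMUSG00000029816) on chromosome 6 from 49036546 to 49070929. Each is annotated as a protein-coding gene, and the values are over the whole gene.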

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

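The tests of mid against low and of high against mid dose, and those of untreated animals and of hepatocyte share, were chosen after the results were seen.

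Effects that differed between groups by the normal test of the difference, with the implied standard error and Benjamini-Hochberg adjustment, numbered 64 genes for low-dose tropifexor against OCA, 225 for mid dose against OCA and 257 for high dose against OCA. Between doses they numbered 43 genes for high against low, 65 for mid against low and 49 for high against mid. The diet effects of the vehicle groups differed for 15 genes. Among these, Onecut1 was higher in the tropifexor than in the OCA vehicle group by 2.42 (log2), and Cyp2b9, whose reads may be shared with the paralogs Cyp2b10 and Cyp2b13, differed by -1.65. Through the tables against lean control with the rescaled error, OCA called 211 genes against its own and 241 against the other vehicle group.

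For 4546 genes called at any tropifexor dose and above the FPKM minimum in each table, effects were ranked along the mean direction of the doses. The effect was smallest at the low and largest at the high dose in 984, as for Nr0b2 with 1.87, 2.55 and 2.63. It was smallest at the low and largest at the mid dose in 1958. The low dose lay between the others in 507 and 258 genes and had the largest effect in 603 and 236. The mid and high doses had more calls (4319 and 4015 against 1813 at the low dose) and smaller errors. Picking genes by a call at any dose therefore favours a low rank of the low dose. No share of each order for unchanged groups was computed, so these counts do not show a dose order. Of 65 genes that differed between low and mid dose, 48 had opposite signs (958 of 1575 with the rescaled error). Only 30 of the 65 were called at both doses with opposite signs (137 of 1575 with the rescaled error). The others with opposite signs lacked a call at 1 dose or both, so their sign there is uncertain. Ccl2 rose by 0.88 at low and fell by 1.62 at mid dose, and Epcam rose by 1.63 and fell by 0.96, in the authors' deposited table. Both differences were called. Cyp8b1 fell by 6.68 and by 5.04 in the authors' deposited table, a difference called only with the rescaled error. The idea that 1 or more of the 4 low-dose animals were untreated was argued against by 13 of the 25 genes that fell at least 8-fold at mid and high dose, whose low-dose 95% interval lay wholly below -2 (log2) (10 with the implied error). A smaller share of hepatocytes would raise the markers of other cell types alike. The medians of low minus mid dose lay 1.88 apart, from 1.81 for cholangiocytes and 1.12 for macrophages to 0.68 for stellate and -0.07 for endothelial cells. The mid dose itself lowered many macrophage and stellate cell genes, so these medians would differ whatever the hepatocyte share. They cannot decide the question, and a smaller share stays open. A list of fetal liver genes had a median at low dose of 0.88, above 99.7% of random lists, and of -0.16 and 0.28 at mid and high dose, so a rise of fetal genes in this group may be part of the pattern, though OCA also stood at 98.6%, and Igf2, called on that list, shares a locus with H19, whose rise at the low dose had been seen. Which dose each group received was assigned by rising order of the names, and a swap of groups was not tested.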

How the results depend on the processing

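The rescaled standard error, the other vehicle group and the comparisons of mid with low and of high with mid dose were chosen after the results were seen. The tables hold group values only, so leaving out replicates, the replicate block, other splits of the samples and a search for outlying animals were not run, and depth sets limits that cannot be stated. No paired analysis was possible because the tables carry no value per animal. For the 92 single genes named in the text, over all tables, 6577 of 7544 alternative values kept their direction and side of the threshold, 866 were no longer called, 92 became called and 9 reversed, all 9 with the other vehicle group: Cish (-0.15 for OCA, 1.88 at low and 2.30 at mid dose), Onecut1 (-0.13 for OCA, 0.77, 0.57 and 0.47 at low, mid and high dose), and Cyp2b10 (0.77) and Cyp2b9 (1.22) for OCA. Of 324 list counts 303 stayed within 1.5 times, and of 150 list percentiles 140 kept their side of the limits used for the outer 5% of random lists. The wider implied error accounts for the lower counts with a normal p from the test statistic and with centred fold changes. The route through lean control called fewer genes for OCA also with the rescaled error, 211 against 731 with the rescaled statistic. Its summed variance counts the lean control 2 times, which lowers the calls by construction. Whether this is the whole cause there, and the causes elsewhere, were not tested.

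With a normal p from the test statistic, the calls were 568 and 609 for the diet in the OCA and tropifexor vehicle groups, 75 for OCA, 253, 1097 and 998 for the low, mid and high doses, and 490, 812, 1012 and 1351 for OCA and the doses against lean control. Centred fold changes with the implied error gave 569, 610, 77, 255, 1127, 982, 490, 812, 1023 and 1336 in that order. At a q of 0.01 OCA kept 368 and the low dose 1181 calls. Taken through the tables against lean control, OCA and the low, mid and high doses had 22, 123, 394 and 397 calls with the implied and 211, 986, 2407 and 2244 with the rescaled error, and 241, 1076, 2431 and 2299 against the other vehicle group.

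Differences at an adjusted p of 0.01 numbered 40 for low dose against OCA, 147 for mid dose against OCA and 37 for mid against low dose. With errors multiplied by 1.5 they numbered 4, 38 and 72 for low, mid and high dose against OCA. With the rescaled error they numbered 797, 1821 and 1739 against OCA, 870, 1575 and 357 for high against low, mid against low and high against mid dose, and 58 between the vehicle groups. With the drug's own vehicle group in both effects, the correlation of diet and drug effects was -0.388 for OCA and -0.108 for the low dose, where its sign turned; the shared vehicle libraries push it below 0.

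With random lists drawn from all tested genes, the percentile of the list median moved past a limit, or back, for the OCA vehicle group in FXR-induced genes (0.375, from 6.58), bile acid synthesis (1.24, from 13.8), glucose production (2.14, from 10.6) and hepatocyte secretory genes (0.11, from 3.75). It did so for the tropifexor vehicle group in bile acid synthesis (0.49, from 4.94), xenobiotic metabolism (2.14, from 9.23) and hepatocyte secretory genes (0.15, from 2.73). The others were fatty acid oxidation at mid dose (9.34, from 0.83), endothelial cells at high dose (3.58, from 1.72) and periportal hepatocytes at low dose (97.4, from 98.8).

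Adjusted over the list alone, the called members were 5 (from 2) for bile acid uptake, 2 (from 1) for endothelial cells, 3 (from 1) for cholesterol efflux and 3 (from 1) for periportal hepatocytes at low dose. For OCA they were 9 (from 4) inflammatory mediators, 12 (from 7) macrophage, 12 (from 7) cholesterol synthesis, 4 (from 2) fatty acid oxidation, 8 (from 5) xenobiotic and 5 (from 3) periportal genes. They were 5 (from 3) periportal and 1 (from 0) pancreas genes in the OCA vehicle group and 1 (from 0) adipose gene at mid dose; fewer genes enter this adjustment. Among members with an FPKM of at least 1, a smaller set, lymphocyte and neutrophil calls were 3 (from 5) and 2 (from 4) in the vehicle groups, 1 (from 3) for OCA, 3 (from 6) at mid and 1 (from 4) at high dose. Cholangiocyte calls were 1 (from 2) and 0 (from 1) at mid and high dose, and cell cycle calls 7 (from 11) in the tropifexor vehicle group.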

Other observations

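The tests of the sex-biased lists at low and mid dose and under OCA were chosen after the results were seen, and all 5 further gene lists used here and in the weighing of the low-dose group were drawn up after the data had been seen.

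Genes known to differ between male and female mouse liver moved with treatment in these male animals. Of 11 male-biased genes, 7 fell and 1 rose at the low tropifexor dose, 3 fell and 6 rose at the mid dose, 5 fell and 4 rose at the high dose, and 4 fell and 1 rose under OCA; adjusted over the list alone, 7 fell and 2 rose, 3 fell and 6 rose, 6 fell and 4 rose, and 5 fell and 1 rose. Susd4, a complement regulator, chosen after its values were seen, was among the falls in each of these groups in the authors' deposited table. Of 17 female-biased genes 11 were tested at the low dose, where 6 rose and 3 fell (7 and 3 adjusted over the list alone), and 10 at the high dose, where 4 rose and 4 fell, also when adjusted over the list alone. At the mid dose 10 were tested, and 3 rose and 3 fell, also when adjusted over the list alone; under OCA 2 of 11 rose (3 adjusted over the list alone). Fmo2, a flavin monooxygenase also chosen after its values were seen, rose in each drug group in the authors' deposited table. In the OCA vehicle group against lean control, the male-biased median lay above 0.76% and the female-biased median above 97.75% of random lists. In the tropifexor vehicle group they lay above 13.7% and 36.6%. The medians of both lists thus also shifted without a drug in the OCA vehicle group. Of 8 fetal liver genes 4 rose at the low dose (5 adjusted over the list alone), among 8 tested.

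The fall of Mup and of some male-biased genes may be part of a shift of sex-biased genes towards the female pattern: at the low dose and under OCA the male-biased median lay above 0.01% and 0.02% of random lists and the female-biased median above 100%, most called members going the same way. At the high dose the median of the female-biased list lay above 99.97% of random lists and that of the male-biased list above 0.78%, but called members of both lists went both ways (4 up and 4 down, 4 up and 5 down), so the medians leave the shift open. At the mid dose 6 male-biased genes rose and 3 fell and their median lay above 99.98%, which argues against such a shift there. Reads moved between near-identical Mup copies would leave their sum in place, but the summed FPKM of 21 Mup genes at the high dose was 3035 against 6752 in vehicle, a log2 ratio of -1.15, and at the low dose that ratio was -1.97, which argues against shared reads as the whole cause at both doses. The ratio was -0.20 at the mid dose and -0.29 under OCA, so for these groups shared reads stay open.

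Of 8 pericentral genes 6 fell at each tropifexor dose, and of 8 periportal genes 1, 8 and 7 rose at the low, mid and high doses, and a shift of liver zonation could reach further genes of both zones. At the high dose 7 of 14 further pericentral genes fell and 1 rose (7 and 2 adjusted over the list alone), and 2 of 8 further periportal genes rose, also when adjusted over the list alone. The median of the further pericentral genes lay above 0.29% of random lists at the high dose, 9.87% at the mid and 0.01% at the low dose, and that of the further periportal genes above 81.3%, 98.9% and 87.1%. At the mid dose 5 further periportal genes rose, and 3 further pericentral genes rose and 4 fell; at the low dose 2 further periportal genes rose and 1 fell, and 1 pericentral gene rose and 8 fell. A fall of pericentral genes alone is argued against by the rises on the first periportal list at the mid and high doses, and no dose had both further lists outside the range of random lists, so whether the shift reaches further genes of both zones stays open.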
